A study of Mus musculus with 64 samples.

How the data were processed

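Open chromatin was measured by ATAC-seq, in which the Tn5 transposase cuts accessible DNA and tags it for sequencing, in 64 livers of C57BL/6J mice. Per the labels, the mice had received an AAV5 vector, a recombinant adeno-associated virus used for gene transfer to the liver, produced either in HEK293 cells (human embryonic kidney cells, the group called 293 here) or in insect cells (the group called sf here). Livers were taken 12, 24 or 57 weeks after dosing. Libraries are named by the letter and number of their titles, such as S7, and 11 letters occur, each within 1 group of vector and week. The labels name separate samples, but not which mouse each number stands for, so p-values measure the spread between these libraries. Untreated livers and the vector integration sites were not analysed here.

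Per the labels' protocols, nuclei from flash-frozen liver were tagmented, amplified and sequenced from both ends on a NextSeq instrument. Per the submitters' processing notes, reads were aligned with BWA and peaks were called with MACS2 on GRCm38.p6; versions, settings, any shift of read ends and any subsampling are not given in the sources used here. The authors deposited 1 peak list per library, so libraries were not pooled before calling. In each list the deposited fold enrichment is a ratio of the pileup at the peak summit to the library's own local background. The deposited p-value and q-value of a peak are given as −log10, and the lowest −log10 q of a list lay between 1.30 and 1.31 over the 64 libraries. The deposited score is 10 times the −log10 q with its decimals removed and was not used in tests. The deposited summit position, in another column, gives the offset of the summit from the start of its peak in bp. The fold and the −log10 p of a peak are the authors' values, and they were used only to rank or filter peaks within a list, apart from the pileup described below.

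Read depth is not given. Whole numbers of fragments at the summit were recovered from the fold enrichment and the −log10 p, which MACS2 computes from the same pileup and background by a Poisson model. A whole number matched for 100% of the peaks of every library, within 0.01 of the −log10 p or 0.1% of it. The median summit pileup of a library lay between 20 and 37 fragments, with a median over libraries of 28. The background shared by the most frequent pairs of fold and p, taken as that of the whole genome, lay between 0.913 and 1.99 fragments. The pileup was an alternative chosen after seeing the data. It was used as log2 of the pileup, with no pseudocount, the highest of the peaks in a region, centred on the median of the library over the regions tested. This log2 summit pileup is the effect size given beside the rank of a region. The fold divides the pileup by the local background, so the rank and the pileup of a region can move in opposite directions.

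Peaks on chromosomes 1 to 19, X and Y were reduced without regard to group to windows of 500 bp around summits, taken in the order of their rank within a list, and windows with a summit in at least 3 libraries were kept. For the main test, 53766 regions that overlapped a peak by at least 1 bp in every library were ranked within each library by the fold enrichment of that peak (the highest where several overlapped), and the ranks were turned into normal scores. A percentile in the text is the rank on a scale from 0 to 100, where 100 is the highest fold enrichment. limma fitted 6 group means to all 64 libraries with 1 shared estimate of the spread per region, and p-values were adjusted by the Benjamini-Hochberg method over all regions, with a threshold of 0.05. Contrasts were the 3 pairs of weeks averaged over both vectors, week 57 against week 12 within each vector, sf against 293 averaged over the weeks and within each week, and the interaction of vector and week. A region is said to have risen or fallen when its adjusted p was under that threshold.

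Regions that are not in every library were tested for presence. Each list was reduced to the same length, 82810 peaks, keeping the highest fold enrichment, and an exact stratified conditional test (two-sided, strata of vector for the weeks and of week for the vectors) compared the number of libraries with a peak. Regions present in fewer than 3 or absent in fewer than 3 of the libraries compared were left out. Numbers of peaks per library were compared by permutation tests (two-sided, 100000 resamples, or exact enumeration where a group had fewer than 10 libraries).

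Positions are 1-based on GRCm38.p6, and gene positions come from a RefSeq gene table of the same build with 49939 genes on the chromosomes used, of which 20130 were named protein-coding genes. That table gives the ends of each gene but no strand, so the plan to use transcription starts was changed: a region whose centre lies within 1 kb of either end of a gene is called a boundary region, and it can lie at the end where transcription starts or at the other one. Exons and introns were not used here. The regions named in the text follow a rule fixed before the data were examined: the 12 called boundary regions with the largest positive and the 12 with the largest negative difference whose sign was the same in both vectors, the 3 highest and 3 lowest called regions farther away (named by the nearest gene end), the 5 gained and 5 lost regions with the largest difference in presence, and, where fewer than 5 regions were called, the 5 boundary regions with the smallest p. Predicted genes were skipped. Regions named outside this rule are said to have been chosen after their values were seen.

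Also fixed before the data were examined were 26 gene lists with 336 symbols, of which 333 were found in the gene table. They cover hepatocyte identity, pericentral and periportal hepatocytes, male-biased and female-biased liver genes, the core clock, cholesterol and bile acid, lipogenesis, lipid droplet and steatosis, fatty acid oxidation, the interferon response, antigen presentation, acute phase and inflammation, the cell cycle, p53 and senescence, endoplasmic reticulum stress, tumour-linked and imprinted loci, coagulation and xenobiotic metabolism, and markers of Kupffer cells and macrophages, T and NK cells, B and plasma cells, neutrophils, endothelial cells, stellate cells and fibroblasts, and cholangiocytes. The plan was to take the region nearest to a transcription start. Without strand, each gene was represented by the boundary region with the highest mean normal score over all 64 libraries, a choice made without regard to group, and 11394 genes had such a region. For 32 of the 230 list genes with one, the region nearest to a gene end was another, and the tests were repeated with that region. The lists with at least 3 such regions, 22 of them, were tested with camera in limma against all other boundary regions at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation and with fry, which is not reported. For all 26 lists, the number of member genes with a boundary peak was counted in the equal-length lists and compared by permutation tests.

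Alternatives fixed before the data were examined were ranking by −log10 p, regions with a peak in at least 90% of the libraries, an overlap of at least 250 bp, only peaks with a −log10 q of at least 10, the title number as a replicate block, a guessed set of sequencing indexes as a block (8 sets read from runs of index numbers, called A to H), leaving out the letters K, U and V, which fill set A, keeping 1 letter per group, the log10 peak number as a covariate, a fit of only the groups compared, other list lengths and all regions of a gene and 10 kb on both sides of it (planned for the side before the start only). The summit pileup, the region nearest to a gene end, the smallest peak width of a library as a covariate and leaving out libraries R7 and S7 were added later. The tests over many regions were tested on simulated data. In 53766 regions made from the real deviations of each library from its group mean, limma recovered 94% of 200 regions changed by 0.5 on the log2 scale and 100% of those changed by 1 for week 57 against week 12, and 98.5% and 100% for sf against 293. The deviations were those of the log2 pileup, ranked after the change was added. Removing the group means also removed the sampling error between groups, so these shares do not give the power of the fold rank test. The presence test recovered 46.0% of 200 regions among 85326 whose share of libraries differed by 0.6 and 0% at a difference of 0.3. Of 200 random lists of 11 genes, camera passed 5.5% at p under 0.05 with no shift and 100% with every member shifted by 0.1 normal scores at week 57. The group means of every gene had been made equal first, so genes outside a list had no difference at all. These shares therefore show only that the direction was read correctly, and not the power or the error rate of camera on real lists. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Some results are not reported here.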

Results

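Open chromatin was profiled in 64 livers of mice that had received an AAV5 vector, to follow the liver genome after gene transfer and to compare vectors from 2 production systems. At week 12 there were 11 livers of the 293 group and 13 of the sf group, at week 24 there were 14 and 7, and at week 57 there were 11 and 8. A library held between 82815 peaks (S7) and 140114 peaks (K5), with a median of 112954, and its peaks covered between 32.2 and 55.6 Mb. The median summit pileup of a library was 20 to 37 fragments. Read totals are not given in the sources used here, so the pileup stands in for depth.

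The first question was how open chromatin changed between week 12 (n = 24) and week 57 (n = 19). The 3 largest increases away from gene boundaries lay on chromosomes 15, 17 and 2. The region at chromosome 15, 20960471 to 20960970, inside a gene and 293971 bp from the nearest end of a named protein-coding gene, Acot10, rose from percentile 51.8 ± 23.7 (SD) to 90.4 ± 7.84, and its log2 summit pileup rose by 0.96 ± 0.12 (SE). The region nearest to Hsf2bp (chromosome 17, 31954667 to 31955166) rose from percentile 32.6 ± 18.6 to 78.1 ± 8.10, and that nearest to Flrt3, which codes for a membrane protein of neurons and other cells (chromosome 2, 140740441 to 140740940), from 46 ± 18.3 to 87.1 ± 8.22. In the other direction, a region between genes, 73013 bp from Mfsd1 (chromosome 3, 67676994 to 67677493), fell from percentile 95.6 ± 4.19 to 62.2 ± 31.8. Inside genes, the region nearest to Arhgap44 (chromosome 11, 65137112 to 65137611) fell from 75.9 ± 16.1 to 33.8 ± 16.2, and that nearest to Pcsk2, the gene of a prohormone convertase (chromosome 2, 143666754 to 143667253), fell from 80.5 ± 15.6 to 41.9 ± 18.8. The log2 pileup had the same direction in all 6, between −1.19 and 1.36.

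Over 53766 regions with a peak in every library, limma with Benjamini-Hochberg adjustment called 1822 regions, 804 higher and 1018 lower at week 57, with a smallest adjusted p of 3.91e-13, and 8866 had an unadjusted p under 0.05. The log2 summit pileup called 5412 regions, 2864 higher and 2548 lower. Of the 1822 regions, 1579 had the same direction by pileup and the rest the opposite one, and 35 of the latter were also called by pileup. In most libraries, 26 of the 1822 lay under the same peak as the called region before them. Age and collection day go with the week, so they cannot be told apart from it.

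**Figure D1:**
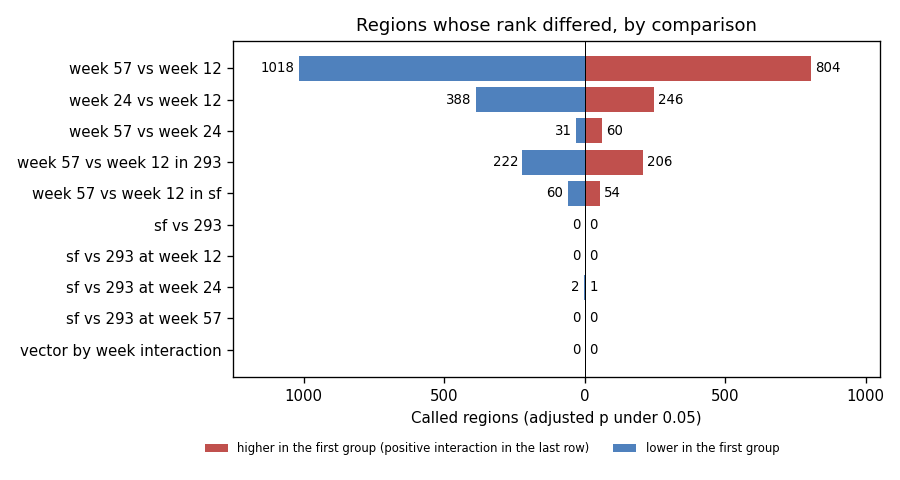
Number of regions called higher (to the right) and lower (to the left) by limma at an adjusted p under 0.05 for each comparison, among 53766 regions ranked by fold enrichment. Week 57 against week 12 gave 804 higher and 1018 lower regions, and sf against 293 gave 0, while the summit pileup called 5412 and 7.

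At gene boundaries, the largest increase was at Dmrta1, which codes for a transcription factor of the DMRT family. A pair of neighbouring regions changed there. They lay under 1 peak in 50 of the 64 libraries, so they are not separate changes. The region at chromosome 4, 89688431 to 89688930, rose from percentile 38.2 ± 17 to 78.4 ± 16.1 and by 2.36 ± 0.13 (SE) in log2 pileup (limma adjusted p = 1.26e-07). The region at 89687851 to 89688350 rose from 45.2 ± 18.8 to 81.8 ± 8.48 and by 2.27 ± 0.12. Sytl1, a gene of vesicle traffic (chromosome 4, 133262900 to 133263399), rose from percentile 18.9 ± 9.06 to 44.5 ± 11.3 and by 0.65 ± 0.08 in log2 pileup. Trh, the precursor of thyrotropin-releasing hormone, rose from 65.1 ± 16 to 86.8 ± 9.42, Hjurp, a chaperone of the centromeric histone, from 0.716 ± 0.504 to 3.54 ± 1.40, Disp3, a gene of the dispatched family, from 31.5 ± 12.4 to 56.9 ± 16, and Prkd1, a protein kinase, from 21.1 ± 13.3 to 40.9 ± 11.4. Their log2 pileup rose by 0.48 ± 0.08, 0.64 ± 0.06, 0.52 ± 0.10 and 0.71 ± 0.11.

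A second set of boundary regions was higher by fold rank but not by pileup. C3, the central complement component (chromosome 17, 57203639 to 57204138), rose from percentile 5.19 ± 5.21 to 14.2 ± 9.32 (limma adjusted p = 0.0200), with a log2 pileup difference in the other direction of −0.11 ± 0.07 (SE). Cxcl1, a chemokine that attracts neutrophils, rose from 24 ± 14.3 to 43.4 ± 7.01, Saa4, a serum amyloid A gene, from 33.4 ± 18.1 to 55 ± 12.3, and Mt1, a metallothionein gene, from 36.6 ± 21.1 to 55.2 ± 7.35, and their log2 pileup differences were in the other direction at −0.25 ± 0.10, −0.09 ± 0.07 and −0.20 ± 0.10. Enho, the gene of the peptide adropin, rose from 40.1 ± 15.2 to 63.8 ± 9.95, with a pileup difference of 0.02 ± 0.06 whose sign flipped under other scalings. None of these 5 pileup differences passed the test, and the local background around them was lower at week 57 by log2 values of −0.64 (C3), −0.73 (Cxcl1), −0.53 (Saa4), −0.64 (Mt1) and −0.42 (Enho). Week 12 livers were widely spread: Mt1 lay between percentile 0.951 and 13.5 in M5, M7, K5, L4, N4, K1 and L6 and between 28.6 and 67.6 in the others. M5 was also low at Saa4 (3.14) and Cxcl1 (4.91). Without any single library these 5 regions still passed, with a highest limma adjusted p of 0.0396 for C3 (without M5) and 0.0206 for Mt1 (without M7).

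**Figure D2:**
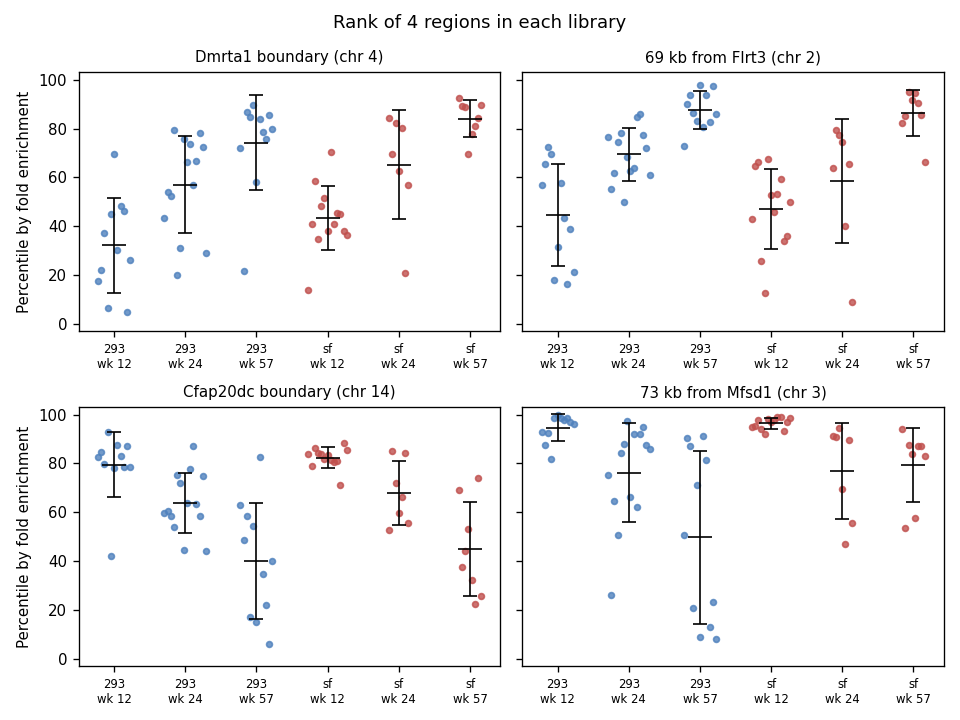
Percentile by fold enrichment of 4 regions (at Dmrta1 and Cfap20dc, and nearest to Flrt3 and Mfsd1) in each library (points), by vector and week, with the mean and SD of each group. Over both vectors Dmrta1 rose from 38.2 to 78.4 and Cfap20dc fell from 81 to 42.2 between weeks 12 and 57, and by summit pileup both moved the same way.

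Among boundary regions that fell by fold rank, the largest decrease was at Cfap20dc (chromosome 14, 8665991 to 8666490), from percentile 81 ± 9.36 to 42.2 ± 21.5, with a log2 pileup difference of −1.18 ± 0.12 (SE; limma adjusted p of the rank 3.37e-08). Map10, a microtubule-associated protein, fell from 52 ± 16.7 to 24.9 ± 13.1, Plekhm3 from 80.2 ± 6.16 to 59 ± 16.8, and Cda, cytidine deaminase, from 36.5 ± 14.1 to 18.8 ± 13.9, with log2 pileup differences of −0.65 ± 0.10, −0.57 ± 0.10 and −0.53 ± 0.12. The replication-dependent histone genes H1f5 (chromosome 13, 21779250 to 21779749) and H2ac15 (21753697 to 21754196) fell from 43.5 ± 13 to 22 ± 9.41 and from 36.6 ± 9.85 to 18.5 ± 9.06, with −1.08 ± 0.10 and −0.90 ± 0.11. Crybb3, a crystallin gene, fell from 7.36 ± 3.86 to 2.17 ± 2.24 with −0.26 ± 0.10. Klhl11 fell from 69.1 ± 11.9 to 42.6 ± 16.2 with −0.02 ± 0.06. Pileup went the other way at Scd1, the stearoyl-CoA desaturase of lipid synthesis (chromosome 19, 44393822 to 44394321), which fell from percentile 17.1 ± 11.6 to 4.34 ± 2.79 by fold rank and rose by 0.71 ± 0.13 in log2 pileup. It also did so at Rgs16, a regulator of G-protein signalling, which fell from 47.3 ± 17 to 20.8 ± 10.9 and rose by 0.56 ± 0.10 in log2 pileup, and at Fbf1, a cilium gene, which fell from 40.8 ± 17.3 to 21.2 ± 16 and rose by 0.22 ± 0.07. Car3, a carbonic anhydrase, fell from 8.27 ± 6.33 to 2.46 ± 3.97 by fold rank, with a pileup difference of the other sign at 0.01 ± 0.07. The background around Scd1 and Rgs16 was higher by 1.17 and 1.05 on the log2 scale.

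Regions that changed lay away from gene boundaries more often than those tested. Of all 53766 regions, 30.3% lay at a boundary, 45.9% elsewhere inside a gene and 24% between genes. Of the 804 higher regions, 154 or 19.2% lay at a boundary (Fisher's exact test, two-sided, p = 6.31e-13), and of the 1018 lower regions 149 or 14.6% (p = 1.12e-31). Regions are not independent replicates, so these p-values describe the lists.

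H1f5 and H2ac15 lie in a block of histone genes that was singled out after its values were seen, and whose ends were set by its lower regions. Within 118 kb of chromosome 13, from 21716011 to 21833889, 14 regions lay at boundaries of replication-dependent histone genes. By log2 pileup 10 of them were lower and 0 higher at week 57 (limma), with a median of −0.67 and a range of −1.08 to −0.10, whereas by fold rank 4 were lower and 2 higher. The mean log2 pileup of the block, relative to the library median, went from 0.06 ± 0.28 (SD, n = 11) through −0.31 ± 0.20 (n = 14) to −0.63 ± 0.18 (n = 11) in 293, and from −0.03 ± 0.14 (n = 13) through −0.30 ± 0.16 (n = 7) to −0.51 ± 0.28 (n = 8) in sf. At week 57, X1 was at 0.07 against −0.92 to −0.40 in the other sf livers. In 293, W1 was at −0.13 against −0.79 to −0.54 in the others. At the 43 histone gene regions outside the block, 0 were lower and 4 higher by pileup, at H1f3, H2bc6, H1f4 and H4c3, with a median of 0.09, and 1 was lower and 2 higher by fold rank. Since the ends of the block were set by its lower regions, no other histone region of chromosome 13 could be lower by pileup. For that chromosome the 0 is therefore not a result.

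**Figure D3:**
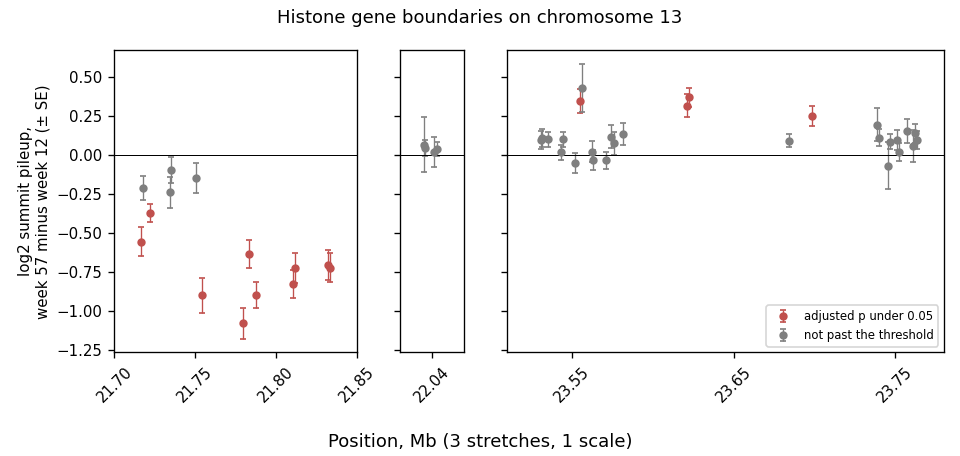
Log2 summit pileup difference between weeks 57 and 12, with SE, of regions at histone gene boundaries in 3 stretches of chromosome 13, coloured where the adjusted p was under 0.05. The 14 regions of the block lie between −1.08 and −0.10 by pileup, while by fold rank 4 were lower and 2 higher.

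Of the gene lists fixed beforehand, acute phase and inflammation was the one called between weeks 12 and 57. By fold rank, 12 of its 13 members with a region were positive, and camera placed the list higher (adjusted p = 0.000133), but adjusted p = 0.367 with an estimated correlation, and by pileup the list was lower, with 3 of 13 positive (adjusted p = 4.02e-05, and adjusted p = 0.0606 with an estimated correlation). Hpx, the heme carrier hemopexin, was the member that rose over all regions, from percentile 25.1 ± 14.3 to 40.1 ± 10.7 (limma adjusted p = 0.0101), with a pileup difference of the other sign at −0.05 ± 0.08. Adjusted over the list alone, 3 rose, with Orm1, an acute phase glycoprotein whose pileup difference had the other sign, and Socs3, an inhibitor of cytokine signalling, beside it. By pileup 2 members fell, the haptoglobin gene Hp by 0.41 ± 0.09 and the metalloreductase gene Steap4 by 0.27 ± 0.06.

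The other 21 lists tested were not called by fold rank. In antigen presentation, 8 of 11 members were positive and the class II gene H2-Eb1 rose from 31.5 ± 10.4 to 41.1 ± 9.99, 1 gene over all regions and 1 adjusted over the list alone (limma adjusted p = 0.0476). Adjusted over the list alone, periportal hepatocyte genes (5 of 9 positive) had 2 higher, Sds and Ass1, and 1 lower, Cyp2f2, and 0 over all regions, with Sds of the other sign by pileup. Lipid droplet and steatosis (5 of 6) had 1 higher, Plin5, and fatty acid oxidation (8 of 10) had 1 lower, Pdk4, adjusted over the list alone and 0 over all regions, and both genes had the other sign by pileup. With 1 boundary region per gene, no member passed either adjustment for hepatocyte identity (7 of 14 positive), pericentral hepatocyte (4 of 9), male-biased (7 of 8) and female-biased liver genes (2 of 6), cholesterol and bile acid (10 of 15), lipogenesis (5 of 11) or the core clock (8 of 15). For Scd1, a lipogenesis gene, the list used the boundary region at chromosome 19, 44407233 to 44407732 (limma adjusted p = 0.152), and not the one at 44393822 to 44394321 that fell. The same was true of interferon response (10 of 18), cell cycle (12 of 16), p53 and senescence (5 of 11), endoplasmic reticulum stress (10 of 13), tumour-linked and imprinted loci (3 of 4), coagulation (11 of 13), xenobiotic metabolism (9 of 12), endothelial (1 of 6), stellate (1 of 4) and cholangiocyte markers (1 of 3). The median of all boundary regions was 0.03 normal scores, so camera placed the clock and the cholesterol list lower although their means and medians were positive, and it placed the interferon list higher although the mean lay just below that median. The median of the pericentral list was negative while its mean was positive and camera placed it higher.

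Xenobiotic metabolism was called by pileup and not by fold rank: 12 of 12 members were positive by pileup with a median of 0.15 (camera adjusted p = 1.53e-06, and adjusted p = 0.0269 with an estimated correlation). By pileup 5 members rose over all regions and 6 adjusted over the list alone. The cytochromes P450 Cyp3a11 and Cyp2c29 rose by 0.63 ± 0.14 and 0.57 ± 0.06 in log2 pileup, Cyp2c29 with the other sign by fold rank, and the transporters Abcc3 and Abcc2 by 0.40 ± 0.07 and 0.23 ± 0.06. The nuclear receptor Nr1i3 rose by 0.32 ± 0.10. Lipogenesis was higher by pileup as well (10 of 11 positive, adjusted p = 0.0255, and adjusted p = 0.481 with an estimated correlation). Male-biased genes were lower by pileup (2 of 8 positive, adjusted p = 0.00713, and adjusted p = 0.0426 with an estimated correlation), as was coagulation (6 of 13, adjusted p = 0.0288, and adjusted p = 0.303 with an estimated correlation), while by fold rank most members of both were positive.

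**Figure D4:**
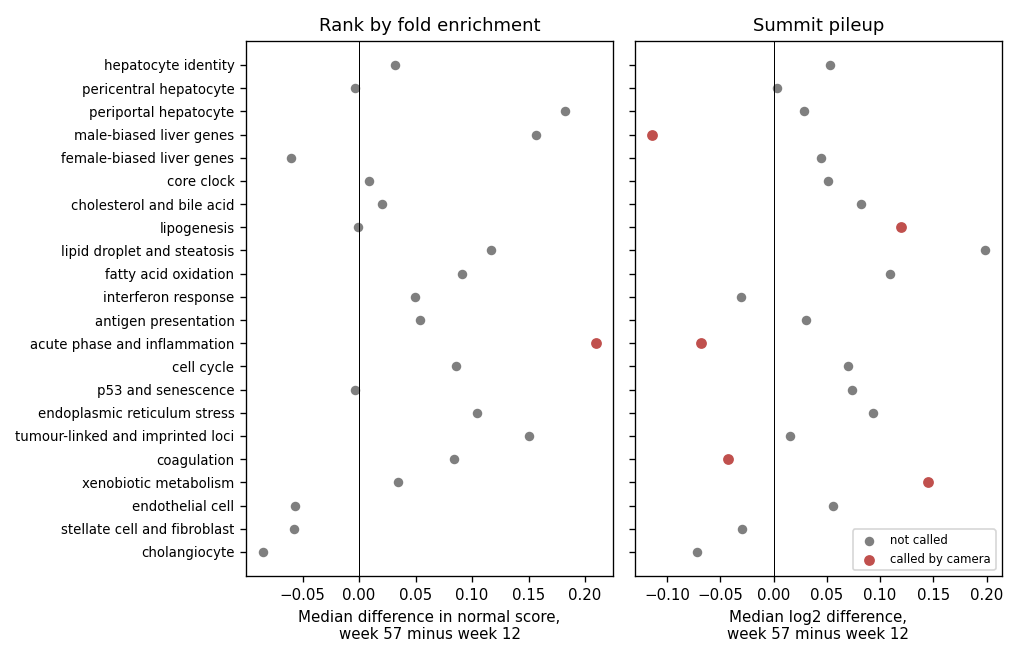
Median difference between weeks 57 and 12 of the members of each gene list, by fold rank in normal scores and by log2 summit pileup. Acute phase and inflammation was higher by fold rank and lower by pileup, and xenobiotic metabolism had a median of 0.15 by pileup.

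Between weeks 12 and 24 (n = 21) part of these changes was already present. Dmrta1 rose by 1.23 ± 0.13 in log2 pileup (limma adjusted p of the rank 0.0158), Sytl1 by 0.40 ± 0.08 (0.00834) and Disp3 by 0.51 ± 0.10 (0.00588). Disp3 was at percentile 32.7 ± 13.3 in 293 and 30.5 ± 12 in sf at week 12 and at 35.1 ± 16 and 70.8 ± 16.1 at week 24. Whether its change between these weeks differed between vectors was not tested. The regions nearest to Arhgap44 and Mfsd1 changed by −0.60 ± 0.11 and −0.78 ± 0.14, and H1f5 by −0.79 ± 0.10. Saa4 rose from percentile 33.4 ± 18.1 to 59.1 ± 12.1 by fold rank, with a log2 pileup difference of the other sign at −0.07. Acute phase genes were again higher by fold rank (12 of 13 positive, camera adjusted p = 0.00104, and adjusted p = 0.452 with an estimated correlation) and lower by pileup (adjusted p = 1.06e-14, and adjusted p = 0.000255 with an estimated correlation). Orm1 was the member that rose over all regions (limma adjusted p = 0.0200), with 5 adjusted over the list alone. Lipogenesis genes were lower by fold rank (2 of 11 positive, adjusted p = 0.00104, and adjusted p = 0.446 with an estimated correlation) and higher by pileup (adjusted p = 0.00212, and adjusted p = 0.331 with an estimated correlation). limma called 634 regions, 246 higher and 388 lower, whereas pileup called 2092, 1040 higher and 1052 lower. Without library S7, S5 or M5 the count was 323, 346 or 366.

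The comparisons of weeks 57 and 24 with week 12 share the week 12 libraries, so their calls are not independent. Of the 1822 regions called at week 57, 1744 had the same sign at week 24, and 117 higher and 143 lower regions were called in both, where independent lists would share 3.68 and 7.35. The differences correlated across regions, which are not independent replicates, with r = 0.60 and a covariance of 0.0155, against 0.44 and 0.00568 with the weeks shuffled. With the week 12 libraries split between the comparisons, the medians over 20 draws were 0.33 and 0.0104. Week 57 against week 24 gave 91 regions, 60 higher and 31 lower (limma), and pileup called 156 higher and 88 lower. The count by fold rank rested on single libraries: it was 176 without S2, 162 without W1, 60 without P2 or X3, 59 without S3, 58 without U2, 54 without W7, 48 without S4 and 46 without V2 or R1. It was 43 without P3, 42 without W4, 41 without U5 or W5, 38 without U3, 37 without U4 or X4, 36 without X10, 35 without X5, 28 without S7 and 24 without S5.

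Both vectors showed the change from week 12 to week 57. In 293 livers (n = 11 and 11) limma called 428 regions in both directions, of which 411 had the same sign in sf. In sf livers (n = 13 and 8) it called 114, 54 higher and 60 lower, of which 111 had the same sign in 293. These comparisons share no library, and 32 higher and 22 lower regions were called in both, where independent lists would share 0.207 and 0.248. Both use the same estimate of the spread of each region, taken from all 64 libraries. A region with a low estimate is more easily called in both, so the numbers for independent lists can be too low. The interaction of vector and week gave 0 regions by limma with 1963 at an unadjusted p under 0.05, and 0 by pileup, so no region was shown to change differently. The 293 count was 251 without M5, 279 without W7 and 281 without W5, and the sf count was 57 without X5, 66 without X4 and 68 without X10.

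Regions that appeared or disappeared in lists of 82810 peaks gave the same comparison for weaker sites. A region between genes, 14793 bp from Phyh, the gene of a peroxisomal enzyme (chromosome 2, 4953286 to 4953785), had a peak in 0 of 24 livers at week 12, 4 of 21 at week 24 and 19 of 19 at week 57. A region inside a gene near Usp6nl, a Rab GTPase activator (chromosome 2, 6327640 to 6328139), went from 0 through 17 to 19 of the same numbers, and that nearest to Tbc1d4, another Rab GTPase activator (chromosome 14, 101540370 to 101540869), from 0 through 15 to 18. The regions nearest to Epm2a, the gene of the glycogen phosphatase laforin, and to Slc39a14, a zinc transporter, both went from 0 through 9 to 18. The 5 lost regions named here lay between 39772 and 373367 bp from the nearest end of a named protein-coding gene. Near Sntb1, a syntrophin gene (chromosome 15, 56280419 to 56280918), 24, 7 and 2 livers had a peak, near Pde1c, a phosphodiesterase gene, 20, 3 and 0, and near Fgfr2, a fibroblast growth factor receptor gene, 19, 4 and 0. Rasal2 went from 24 through 11 to 4 and Fnip2 from 24 through 5 to 4.

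The exact stratified test with Benjamini-Hochberg adjustment called 933 of 85326 regions between weeks 12 and 57, 573 gained and 360 lost, with a smallest adjusted p of 2.97e-07. Of the regions tested 13.8% lay at a gene boundary, against 11.2% of those gained and 10% of those lost. Changes in presence can follow the rank of a region as well as its opening, since every list was held to the same length.

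**Figure D5:**
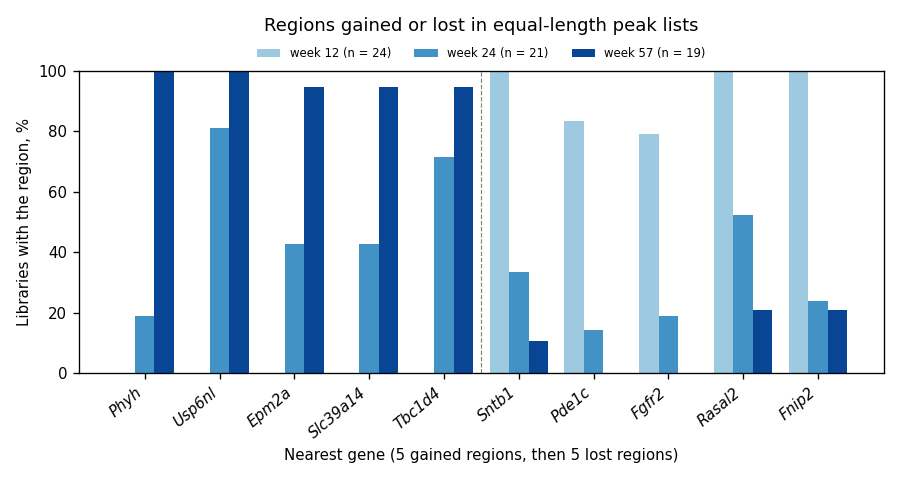
Share of livers with a peak at weeks 12, 24 and 57, both vectors together, for the 5 gained and 5 lost regions with the largest differences among those called in lists of 82810 peaks. The region near Phyh had a peak in 0 of 24 livers at week 12 and in 19 of 19 at week 57.

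The second question was whether livers given the sf vector (n = 28) differed from those given the 293 vector (n = 36). No named gene passed the test. The boundary regions with the smallest p, none of them past it (limma adjusted p = 0.411), included Atf4, a transcription factor of the stress response, at percentile 15.6 ± 12.8 (SD) in 293 and 6.61 ± 9.68 in sf, and Syce2, a synaptonemal complex gene, at 38.6 ± 8.87 and 29.8 ± 6.36. They also included Zbtb8a at 36.8 ± 9.05 and 27.2 ± 10.7, Mtln, a mitochondrial micropeptide gene, at 74.4 ± 7.80 and 81.9 ± 7.37, and Gbp10, a guanylate-binding protein gene, at 94.5 ± 3.59 and 97.1 ± 1.52. limma gave 0 regions with 3588 at an unadjusted p under 0.05 and a smallest adjusted p of 0.233, and pileup gave 7. With 200 simulated regions changed by 0.5 on the log2 scale in sf livers, 98.5% were recovered. That simulation ranked log2 pileup and not fold enrichment, and it held no sampling error between group means. It therefore does not give the power of the fold rank test, and the size of difference that test could detect is not known.

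Within single weeks, sf and 293 gave 0 regions at week 12 (2498 at an unadjusted p under 0.05, and 1 by pileup) and 0 at week 57 (2268, and 0 by pileup). At week 24 limma called 3 regions, named after their values were seen, and pileup called 0. Disp3 was at percentile 35.1 ± 16 in 293 (n = 14) and 70.8 ± 16.1 in sf (n = 7; limma adjusted p = 0.0313). The region nearest to Carmil1 (chromosome 13, 24144055 to 24144554) was at 93.6 ± 3.13 and 76.2 ± 12.2 (limma adjusted p = 0.0120), and that nearest to Marchf5 (chromosome 19, 37242685 to 37243184) at 73.1 ± 5.80 and 51.3 ± 11.2 (limma adjusted p = 0.0184). The count was 0 without S3, 1 without S1, S4 or S7 and 5 without S6. Disp3 no longer passed without P1, P3, P4, P6, P7, R3, R4, R5, S1, S2, S3, S5 or S7 (limma adjusted p from 0.0515 to 0.196), Carmil1 without S3 or S4 (0.0520 and 0.0951) and Marchf5 without S1, S3, S4 or S7 (0.0569 to 0.196).

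None of the 22 lists differed between sf and 293 by fold rank with camera. By pileup 4 did: hepatocyte identity was lower (adjusted p = 0.0147, and adjusted p = 0.396 with an estimated correlation), as were acute phase and inflammation and xenobiotic metabolism (both adjusted p = 0.00921, and adjusted p = 0.324 with an estimated correlation). Endothelial markers were higher with 6 of 6 positive, among them Cdh5 and Kdr, genes of endothelial junctions and growth factor signalling (adjusted p = 0.00063, and adjusted p = 0.241 with an estimated correlation). Over all regions 0 members of these 4 lists passed by pileup, and adjusted over the list alone 1 acute phase gene and 3 xenobiotic genes were lower. By fold rank 0 members of any list passed over all regions, and adjusted over the list alone 1 did, Tert, the catalytic subunit of telomerase, higher in sf (limma adjusted p = 0.0102) and with the same sign by pileup. In equal-length lists, 0 of 97477 regions differed in presence by the exact stratified test, with 3812 at an unadjusted p under 0.05. The smallest p at a boundary was at Prr5, a subunit of the mTORC2 kinase complex, with a peak in 33 of 36 livers of 293 and 13 of 28 of sf (exact p = 0.00021, adjusted p = 1). The others, all with an adjusted p of 1, were Ecd (17 and 24 livers), Cfap53 (12 and 1), Ldb1 (28 and 12) and Zfp768 (34 and 16).

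The number of peaks per liver did not separate the groups. It was 113302 ± 11225 (SD, n = 24) at week 12 and 114534 ± 9956 (n = 19) at week 57, a difference of 1231 whose sign changed under other settings (permutation test, two-sided, p = 0.709). It was 115130 ± 9413 (n = 36) in 293 and 111681 ± 11632 (n = 28) in sf (p = 0.196). At week 57 sf livers had 108250 ± 9915 peaks (n = 8) and 293 livers 119104 ± 7419 (n = 11; exact permutation p = 0.0144, adjusted p = 0.0720 over 5 comparisons), and the change over time did not differ between vectors by permutation (p = 0.0920). The share of peak regions at gene boundaries was 23.1% ± 0.343 at week 12 and 23.1% ± 0.166 at week 57 (permutation adjusted p = 0.719).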

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

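The tests in this part were chosen before the data were examined, but not everything they were applied to. The week 24 regions near Carmil1 and Marchf5 were named, and the histone block was singled out, after their values were seen. In the sf groups of weeks 24 and 57, single libraries far from the others were searched for by Dixon's ratio, the gap to the nearest library over the whole range. The search covered the named regions, the peak number and the mean log2 pileup of the histone block. Of 78 groups 12 had such a library, where chance gives about 1 in 20, or 3.9. No biological explanation was tested for these libraries.

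At week 24 (n = 7), S4 was apart at Disp3 (percentile 37.7 against 67.4 to 84.8 in the others, ratio 0.632) and at the region near Carmil1 (50 against 74.7 to 85.5, ratio 0.695). S5 was apart at Enho (69.1 against 42.9 to 54.1, ratio 0.574), S3 at Crybb3 (12.9 against 0.646 to 3.46, ratio 0.770) and S7 at Atf4 (31.8 against 0.185 to 6.49, ratio 0.801).

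At week 57 (n = 8), X1 was higher than the others at 3 genes that fell with time by fold rank, of which Rgs16 and Scd1 rose by pileup: Rgs16 (57.1 against 19.8 to 29.8, ratio 0.732), Scd1 (13.5 against 1.93 to 5.10, ratio 0.726) and H2ac15 (45.5 against 2.74 to 22.6, ratio 0.535). X3 was apart at Car3 (18 against 0.170 to 3.51, ratio 0.812). X10 was lower near Flrt3 (66.4 against 82.2 to 94.9, ratio 0.553) and near Carmil1 (70.2 against 82.5 to 93.0, ratio 0.541), and X7 was higher near Marchf5 (78.4 against 43.4 to 59.6, ratio 0.537).

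The lists also hold 444 peaks on the mitochondrial chromosome over the 64 libraries, between 3 and 17 in each, which no comparison used. Without untreated livers there is no background to set beside them.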

How the results depend on the processing

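The pileup alternatives, the peak width covariate, the fit without R7 and S7, index set A alone and the region nearest to a gene end were chosen after seeing the data, and the others before. Of values not listed here, 122 of the counts and differences and 464 of the values of named regions and lists kept their direction and their side of the threshold, or for counts lay within 1.5 times, and 40 kept their direction but not their side. The cause was not tested for any change below unless one is given.

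Week 57 against week 12 stayed between 1604 and 2319 regions with the replicate or index block, without K, U and V, with 1 letter per group, with either covariate and with only the groups compared. It was 3780 by −log10 p, 3366 with a peak in 90% of libraries (more regions tested), 780 with an overlap of 250 bp and 882 with a −log10 q of at least 10 (fewer tested). By pileup it was 5827 as a rank, 5412 as log2 and 6030 as log2 with the index block. Week 24 against week 12 gave 1246, 1033, 277 and 300 under the first 4 of these, and by pileup 2377, 2092 (1040 higher, 1052 lower) and 2896 (1741 higher, 1155 lower), against 246 higher and 388 lower by fold rank. It gave 992 without K, U and V, 393 with 1 letter per group, 262 without R7 and S7 and 416 with only the groups compared.

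Week 57 against week 24 gave 147 with 90% of libraries, 1 with 250 bp, 33 with the stricter q (15 higher, 18 lower, against 60 and 31), 36 with the replicate block, 11 without K, U and V, 1 with 1 letter per group and 30 without R7 and S7. By pileup it gave about 2.2e+02 (152 higher, 71 lower) as a rank and 2.4e+02 (156 higher, 88 lower) as log2.

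Within 293, week 57 against week 12 gave 1287 by −log10 p, 1067 with 90% of libraries, 127 with 250 bp, 172 with the stricter q, about 2.4e+02 without K, U and V (111 higher, 124 lower), 266 with 1 letter per group, and by pileup 2454, 2561 and 3251. In index set A alone limma gave 0 regions, with 3960 at an unadjusted p under 0.05, from 8 libraries. Within sf it gave 380, 308, 28 and 30 under the first 4, 172 with 1 letter per group, 179 with the width covariate, and by pileup 867, 778 and 819.

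Between sf and 293 limma gave 4 regions by −log10 p, 3 with the index block and 7 by each pileup alternative, against 0. At week 12 it gave 1 by −log10 p, 1 with the replicate block and 1 by log2 pileup, against 0, and at week 57 1 with 90% of libraries. At week 24, against 3, it gave 0 by −log10 p (4166 at an unadjusted p under 0.05), by log2 pileup (4453), by log2 pileup with the index block (5287) and with only the groups compared (3133), and 1 with 1 letter per group, by pileup rank and without R7 and S7.

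Libraries with the same title number were on average more alike than other libraries. Not every pair of them had an r over 0.1 (lowest −0.36), so the numbers were not taken as pairs. Their mean r was 0.0704 against −0.01 for different numbers, and 35.9% of libraries were closest to one of the same number, where 13.8% would be by chance. For the index sets these were 0.101, −0.01, 34.4% and 11.8%. Index set explained 41.1% of component 1 of the ranks (15.9% of the variance) and group 5.14%. Component 1 also followed the smallest peak width of a library, with an absolute r of 0.714. Of component 4 (4.19% of the variance) group explained 54.7% and index set 8.89%. With the title number as a replicate block, 57 against 12 gave 1907 regions and 24 against 12 gave 946.

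In presence, week 57 against week 12 gave about 2.2e+02 regions among the strongest 20000 peaks (131 gained, 86 lost), 334 with 250 bp and 174 with 1 letter per group, and 636 to 1361 under the others. The peak number difference of 1231 changed sign to −0.393 Mb as covered length, −1109 without K, U and V and −1873 with 1 letter per group. The sf difference kept its sign, between −2380 and −3894.

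At week 57 against week 12, 5 lists were called with all regions of a gene and 10 kb beside it, 0 with an estimated correlation, 5 by pileup, 6 by pileup with all regions and 5 by pileup with the index block, against 1. At week 24, against 2, these were 5, 0, 6, 8 and 7, and for sf against 293, against 0, the pileup alternatives gave 4, 9 and 6. The acute phase list changed direction by pileup at week 57 (adjusted p = 4.02e-05, with all regions 2.25e-06, with the index block 6.04e-06) and at week 24 (1.06e-14, 1.52e-09 and 3.17e-14), and lipogenesis did so at week 24 (0.00212, 0.000105 and 0.00514). These come from camera, and the fold divides by the background, which the pileup leaves out.

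Named regions changed sign, in log2 pileup, log2 pileup with the index block and pileup rank in that order, at C3 (−0.11, −0.10 and −0.094), Cxcl1 (−0.25, −0.28 and −0.46), Mt1 (−0.20, −0.27 and −0.33), Saa4 (−0.092, −0.10 and −0.10), Fbf1 (0.22, 0.19 and 0.22), Rgs16 (0.56, 0.49 and 0.77) and Scd1 (0.71, 0.64 and 0.94). Rgs16 (0.15) and Scd1 (0.21) also did so by −log10 p, Car3 in the first (0.0077) and second (0.014), and Enho in the second (−0.012) and the last (−0.015). In the presence test, a difference of 0.6 in the share of libraries was recovered in 46% of simulated regions and one of 0.3 in 0%. The effect of depth on it was not tested.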

Other observations

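The splits of the libraries were planned before the data were examined, and the tests of index sets, fragment length, the histone block and the acute phase loci were chosen after the results were seen.

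In 100 splits of the libraries, the real one included, no other split called as many regions in the comparisons that follow. These were weeks 57 and 12 (1822, highest of the other splits 19), weeks 24 and 12 (634, highest other 61) and weeks 57 and 24 (91, highest other 1). They also held weeks 57 and 12 within 293 (428, highest other 33) and within sf (114, highest other 1), and the regions gained or lost (933, highest other 1). In each of these 1 split, the real one, was as large, and 100 splits cannot show a smaller share. Libraries were shuffled singly, while each title letter lies within 1 group, so a difference between letters was not tested. For weeks 57 and 24 the week 12 libraries were shuffled as well. That count was 11 without K, U and V and 1 with 1 letter per group. Chance cannot be excluded for sf against 293 at week 24 (3, highest other 13, with 6 splits as large). For sf against 293 over all weeks, at week 12, at week 57, for the interaction and in presence the real count was 0 (highest others 5, 5, 3, 50 and 0), so all 100 splits were as large. limma and the exact test gave 3588, 2498, 2268, 1963 and 3812 of these regions an unadjusted p under 0.05, and pileup called 7, 1, 0 and 0 of the first 4.

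The change from week 12 to week 57 was weighed against a batch that follows the index sets, which are a guess from the library indexes. Index set A holds 4 libraries of week 12 (K) and 4 of week 57 (U) within 293. Of 1604 regions called without K, U and V, 1247 or 77.7% had the same sign inside the set, and of the 70 ways to name 4 of its 8 libraries 1 reached that share, the highest other being 73.8%. With the smallest peak width of a library, a stand-in for fragment length, as a covariate, 2319 regions were called in place of 1822. The mean of this width was 109.4 bp in 293 and 109.6 in sf at week 12, and 109.0 and 109.4 at week 57. Since these means were close, the covariate had little room to lower the count, and the higher count decides nothing about fragment length. The means show only that the stand-in itself hardly differed between the weeks. Age, time since dosing and collection day go with the week and stay open.

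The lower pileup of the chromosome 13 histone block was weighed against a loss of copies of the segment, reads shared between near-identical histone genes and fewer dividing cells. A loss of copies of the segment would lower all of its regions alike, but 6 of the 14 histone regions of the block lay farther than 3 SE from its median of −0.67, which argues against it as the whole cause. That comparison used the summit pileup alone and did not weigh the local background of the block. Fewer dividing cells would lower replication-dependent histone genes as a set. Over all 57 histone regions, with no split by place, the median log2 difference was 0.043 with a spread of 0.118 (MAD). Of these regions 10 were lower and 4 higher, so the set as a whole was not lower. How far it should fall is not known, because the block and its median were picked for low values. The comparison therefore cannot decide how much of the fall in the block came from fewer dividing cells. Shared reads stay open as well, because the median of all histone regions does not show whether reads are shared within the block alone. A change of chromatin with age or time since dosing stays an untested hypothesis.

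Acute phase genes were higher by fold rank and lower by pileup. At the 32 regions inside these genes or within 10 kb of them, but away from their boundaries, 5 were lower by pileup and 0 higher, in 4 of 14 loci (Orm1, Saa1, Saa2 and Socs3), with a median log2 difference of −0.08. Of these regions 15.6% were lower and 0% higher, against 4.74% and 5.33% of all regions tested. Whether opening fell over the whole locus, and with it the local background that the fold divides by, stays open, because most loci held no lower region away from the boundaries. That condition was set after these values were seen, and the first one, more lower than higher and a larger share lower than of all regions, was met.

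Member genes of each list with a boundary peak were counted per library in the equal-length lists. Fatty acid oxidation genes rose from 8.92 ± 1.18 (SD) at week 12 to 10.1 ± 0.848 at week 57 (permutation test, two-sided, p = 0.00074, adjusted p = 0.0192 over 26 lists), and the other 25 lists did not pass. The rise rested in part on Cyp4a14, a fatty acid hydroxylase gene with a peak in 9 of 24 livers at week 12, 15 of 21 at week 24 and 19 of 19 at week 57. Without it the count was 8.54 ± 1.10 and 9.05 ± 0.848 (permutation adjusted p = 0.568), while Ppara went the other way, from 2 of 24 to 1 of 19, and 6 of the 12 members had a peak in every library. The run without Cyp4a14 was chosen after the result was seen. Among these, Kupffer cell and macrophage markers were at 5.0 ± 1.79 and 3.95 ± 1.54 (permutation adjusted p = 0.298), T and NK cell markers at 4.46 and 5.0 (0.298), B and plasma cell markers at 2.75 and 2.89 (0.812), and neutrophil markers at 0.333 and 0.263 (1). Between sf and 293 no list passed, the smallest p being that of Kupffer cell markers, 5.25 ± 1.78 and 4.28 ± 1.5 (permutation p = 0.0255, adjusted p = 0.662). All 16 cell cycle genes had a peak in every library.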
